A study of Mus musculus with 6 samples.

How the data were processed

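Uterine NK cells were sorted from implantation sites at gestational day 8.5, and per the labels' protocols the sites of each mouse were pooled, digested and enriched for CD45.2 before live CD3-negative, CD122-positive cells were collected. The series title adds NK1.1 to the gate. Per the labels' protocols, total RNA of the sorted cells was amplified with the NuGEN Ovation RNA-Seq System v2 and sequenced on an Illumina HiSeq2500; a second kit named there is given no separate role. The 6 libraries fall into 2 groups of 3 by their titles, WT and Gab3-KO.

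The values are raw read counts per gene symbol, deposited by the authors as 1 table with 1 column per library, with no normalization seen in the values. The genome build was mm10, per the submitters' processing notes. The aligner, the counting tool, the gene annotation and the handling of strand and of reads that match several genes are not given in the sources used here. Paralogs, overlapping genes and antisense partners may therefore share reads, and values of such genes are uncertain. The 6 columns were matched to the samples by the sample codes in their names, and 0 columns of other samples were left aside. Total reads per library ran from 12651966 to 27820876. A row for reads without a gene held 5.31% to 5.60% of them and was left out of library sizes and tests, which left 31497 genes, of which 18611 had at least 1 read.

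Counts were tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood F test with robust empirical Bayes moderation, with TMM factors of 0.976 to 1.02 and the edgeR expression filter (minimum count 10), which kept 13935 genes. The model held the group alone. P-values were adjusted by Benjamini-Hochberg over all genes tested, and a gene is said to be called, or to have risen or fallen, at an adjusted p below 0.05. CPM values use TMM-scaled library sizes, and means are given with the SD of 3 libraries. Fold changes are on the log2 scale, libraries labelled Gab3-KO over WT, with the standard error of the fit. Single values of 3 against 3 were compared with an exact two-sided permutation test, which cannot go below p = 0.1.

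The tests, the alternatives, 38 gene lists and the rule for named genes were fixed before the data were examined. Lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted over the 37 lists that had tested members, and beside it with an estimated correlation and with fry. Camera compares the moderated test statistics of the members with those of other genes and does not test the median fold change given beside it. Their signs can differ, as for uterine epithelium (median 0.37, camera direction down). None of the 5 calls by camera held with an estimated correlation. The lists hold 815 distinct symbols, of which 62 had no row. Symbols were matched exactly, without older names. The list of mitochondrially encoded RNA had no rows and was not tested. Gab3 was always named. Named by size were the called genes with at least 5 CPM in a group mean, no overlap between the groups and no predicted or clone name, up to 12 per direction, which gave 8 higher and 12 lower genes. Up to 4 members with the smallest p were named from each list described, together with a fixed set of NK cell genes. Gzmf, Gzmn, Ear2, AK156673, Gm11711, further members called over a list alone and the genes of the closing section outside these rules were chosen after their values were seen. Coordinates are those of GENCODE M21 on mm10.

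Depth and amplification may both have limited precision, and the error of amplification was not measured. A floor of 3 reads corresponds to 0.114 to 0.250 CPM in single libraries. Between 13518 and 16089 genes were detected per library, yet genes with 1 to 15 reads made up only 4.87% to 19.7% of them, fewer in 5 libraries than in WT replicate 2, so low counts carry more error than counting alone gives. Counting intervals (95%) and floors cover counting error only, since reads carried no molecular identifiers. Replicates of a group differed by far more than sampling noise (chi-square per degree of freedom 19.0 to 73.9), so none was counted as a repeat of another. The common biological coefficient of variation was 0.616.

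The procedure was tested on simulated data, in 3 simulations of the comparison over 13935 genes with 200 changed genes each. Genes changed 1.5-fold, 2-fold and 4-fold were called in 5.47%, 32.3% and 57.6% of cases, and in 20.0%, 95.8% and 100% where the mean exceeded 64 CPM. Of 41205 unchanged genes, 16 were called. A raised list was called in 3 of 3 simulations and unchanged lists in 0 of 300. The simulated genes varied independently, so these counts do not cover lists whose members move together.

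Alternatives were RLE, upper-quartile and no composition factors, DESeq2 1.42.0, limma-voom, edgeR without robust moderation, no filter, a filter at 10 CPM in 3 libraries, the replicate number as a block, a correction for GC content and transcript length (loess, span 0.4, fitted on genes with a mean log2 CPM over 3 and available for 12350 tested genes, 88.6%) with and without the block, an adjusted p below 0.01, a test against a fold change of 1.5, and leaving out each library in turn. Ribosomal protein genes, an NK lineage list and cut-offs on its expression were added after seeing the data. Figures were drawn with matplotlib 3.10.9.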

Results

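The series measured gene expression by RNA sequencing in uterine natural killer (NK) cells, the innate lymphocytes that gather in the lining of the pregnant uterus. The cells were sorted from mouse implantation sites at gestational day 8.5. Of the 6 libraries, 3 came from wild-type (WT) C57BL/6 matings and 3 carried the label Gab3-KO, for matings of Gab3KO males with Gab3KO females. Reads assigned to genes numbered 22422127, 15546919 and 22032734 in WT replicates 1 to 3 and 21726638, 11978072 and 26330808 in Gab3-KO replicates 1 to 3. The protocol pooled the sites of each mouse, but no label states which mouse a library came from. The p-values therefore measure the spread between these samples, which may be in part technical.

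Gab3 encodes an adaptor protein that links activated cytokine receptors to PI3K and MAP kinase signalling. Its reads were not lower in the libraries labelled Gab3-KO. Gab3 (X chromosome, mm10 positions 74966843 to 75085458, minus strand) stood at 21.9 ± 5.23 CPM (read counts scaled to a common library size; SD, n = 3) in WT and at 84.1, 22.8 and 17.6 CPM in the libraries labelled Gab3-KO replicates 1 to 3. These rested on 388 to 451 reads per WT library and on 1851, 278 and 464 reads. The log2 fold change was 0.93 with a standard error of 0.57 and an adjusted p of 0.867 by edgeR, and it was -0.12 (adjusted p = 0.985) without replicate 1 of that group. Counts per gene cannot show which part of a transcript was read, and the labels do not say which part of Gab3 was altered, so the gene's reads neither bear out nor contradict the labels. The group is called the libraries labelled Gab3-KO throughout, and every direction below rests on those labels. The related adaptors Gab1 and Gab2 had log2 fold changes of -0.14 (SE 0.76) and 0.05 (SE 0.20), and neither passed the test.

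**Figure D1:**
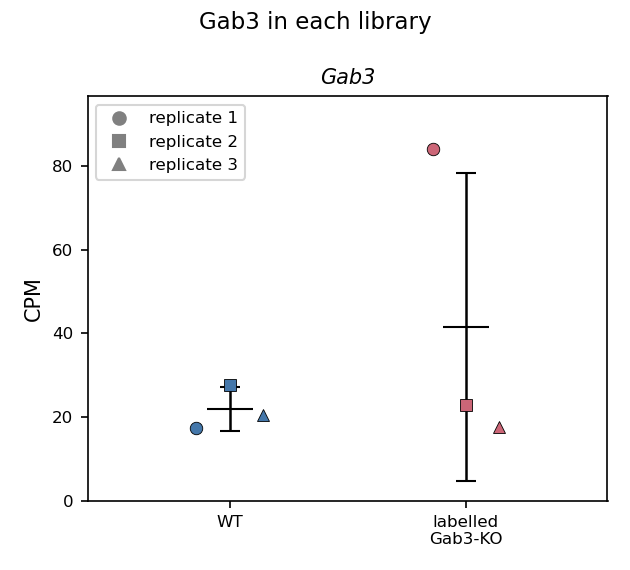
Gab3 in CPM (vertical axis, linear from 0) in the 3 WT libraries and the 3 libraries labelled Gab3-KO; the bars give the mean and SD of each group. Replicate 1 of the second group stands at 84.1 CPM and the other 5 libraries lie between 17.5 and 27.7 CPM.

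The comparison asked how uterine NK cells labelled Gab3-KO differed from WT in gene expression. Genes for 4 granzymes (Gzmd, Gzme, Gzmf and Gzmg), which are proteases of cytotoxic granules, and for 2 granzyme-inhibiting serpins fell in the libraries labelled Gab3-KO, while other granzyme genes did not pass. Spp1, which encodes the secreted glycoprotein osteopontin, dropped from 3866 ± 364 to 1557 ± 311 CPM (SD, n = 3 each; log2 fold change -1.31, SE 0.13, adjusted p = 0.000874). Khdc1a, a member of a small cluster of KH-domain genes, rose from 43.3 ± 4.24 to 189 ± 14.4 CPM (log2 fold change 2.12, SE 0.14, adjusted p = 1.24e-05), and Vcan, the gene for the matrix proteoglycan versican, rose from 34.0 ± 0.396 to 82.6 ± 8.90 CPM (1.28, SE 0.18). In all, 26 of 13935 tested genes passed an adjusted p of 0.05, 8 of them higher and 18 lower in the libraries labelled Gab3-KO. At an unadjusted p of 0.05, 980 genes passed, where 697 are expected by chance.

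Higher expression was also found for 3 genes with intracellular roles. Zfp36, which encodes an mRNA-destabilising zinc finger protein, rose from 346 ± 20.6 to 572 ± 94.8 CPM (log2 fold change 0.72, SE 0.12). Samhd1, the gene for a dNTP hydrolase, rose by 0.53 (SE 0.09), and Tulp4 by 0.87 (SE 0.15). Khdc1b rose by 2.69 (SE 0.48). It is closely related to Khdc1a, and reads may have been divided between such paralogs. A pair of immunoglobulin-related genes was higher as well. Igha, the constant region of IgA, had 1.24 ± 1.10 CPM in WT and 17.1 ± 6.53 CPM in the libraries labelled Gab3-KO (log2 fold change 3.77, SE 0.68). Jchain, which joins IgA and IgM chains, had 0 reads in WT and 521 in the other group, which is 170-fold higher against a floor of 3 reads over the group. This bound treats reads as independent. It leaves out copies made by amplification and the spread between libraries, so the true difference may be smaller. Igha and Jchain are markers of antibody-secreting cells and were thinly covered, and Jchain was not called without Gab3-KO replicate 2 (adjusted p = 0.195) or Gab3-KO replicate 3 (adjusted p = 0.0757). Khdc1b was called in none of the 6 fits that left out 1 library, with adjusted p-values of 0.0767 to 0.196. Samhd1 and Tulp4 were each called in 1 of these fits, and Zfp36 and Igha each in 2. Zfp36, Tulp4, Igha and Khdc1b were not called by edgeR without robust moderation. Igha and Jchain were not called by limma-voom or with the filter at 10 CPM in 3 libraries.

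Among the lower genes, Scin, an actin-severing protein gene, dropped from 267 ± 15.3 to 116 ± 15.004 CPM (log2 fold change -1.20, SE 0.12, adjusted p = 0.000711). Car2, the gene of a cytosolic carbonic anhydrase, decreased by 0.88 (SE 0.10) and Slc39a14, a zinc transporter gene, by 0.85 (SE 0.13). Slc39a14 was called in only 3 of the 6 fits that left out 1 library. Ear3, of the eosinophil-associated ribonuclease family, had 991 reads in WT and 2 in the libraries labelled Gab3-KO, a ratio of 505 with a 95% counting interval of 140 to 4180. Its paralogs may share its reads, and Ear2 was at 83.1 ± 25.7 CPM in WT and 91.9 ± 15.8 CPM in the other group. AK156673 and Gm11711 were named after their values were seen. They had 597 and 562 reads in WT and 0 in the libraries labelled Gab3-KO, which is 203-fold and 191-fold lower against a floor of 3 reads over the group. These bounds and the interval of Ear3 treat reads as independent. They leave out copies made by amplification and the spread between libraries. AK156673 was called in 4 and Gm11711 in 3 of the 6 fits that left out 1 library.

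Several genes of the cytotoxic granule fell. Of 19 tested members, 6 were lower and 0 higher over all genes tested, and 9 were lower when adjusted over the list alone. Gzmd fell from 5261 ± 107 to 2981 ± 178 CPM (log2 fold change -0.82, SE 0.07, adjusted p = 0.000201), Gzme by 0.87 (SE 0.09), Gzmg by 0.99 (SE 0.10) and Gzmf by 0.63 (SE 0.08). Gzmd (mm10 chromosome 14, 56129556 to 56132608), Gzme (56117626 to 56120625) and Gzmg (56156582 to 56159579) are neighbours of similar sequence, so the value of each single gene is uncertain. Summed over Gzmd, Gzme, Gzmf, Gzmg and Gzmn, the cluster held 14772 ± 758 CPM in WT and 8605 ± 703 CPM in the libraries labelled Gab3-KO, with no overlap (exact two-sided permutation p = 0.1, the smallest that 3 against 3 allow). Serpinb9 and Serpinb6b, on chromosome 13, encode inhibitors of granule proteases. They dropped from 328 ± 16.1 to 166 ± 20.4 CPM (-0.99, SE 0.11) and from 126 ± 10.8 to 51.2 ± 0.542 CPM (-1.29, SE 0.15).

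Other granule genes did not pass the test over all genes. Prf1, the gene of pore-forming perforin, was at 1141 ± 48.4 CPM in WT and 752 ± 151 CPM in the libraries labelled Gab3-KO (log2 fold change -0.60, SE 0.12, adjusted p = 0.0839). It passed in DESeq2 (adjusted p = 5.06e-05) and in limma-voom (adjusted p = 0.00838). Gzmb was at 4318 ± 370 and 3883 ± 502 CPM (-0.15, SE 0.10) and Gzma at 592 ± 76.3 and 469 ± 82.5 CPM (-0.33, SE 0.13). Gzmm (-2.02, SE 1.87), Gzmk (-1.70, SE 2.03) and Serpinb9b (-1.31, SE 1.24), named after their values were seen, were thinly covered. The median of the list was -0.60, and the list was lower than other genes by camera with the preset correlation (adjusted p = 6.39e-07 over 37 lists). With the filter at 10 CPM the median was -0.30. The call was lost with the correlation estimated from the data (adjusted p = 0.295 with an estimated correlation), while fry, which asks only whether members move one way, gave an adjusted p of 0.0126. Gzmf was not called after correction for GC content and transcript length (-0.47, adjusted p = 0.0627).

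**Figure D2:**
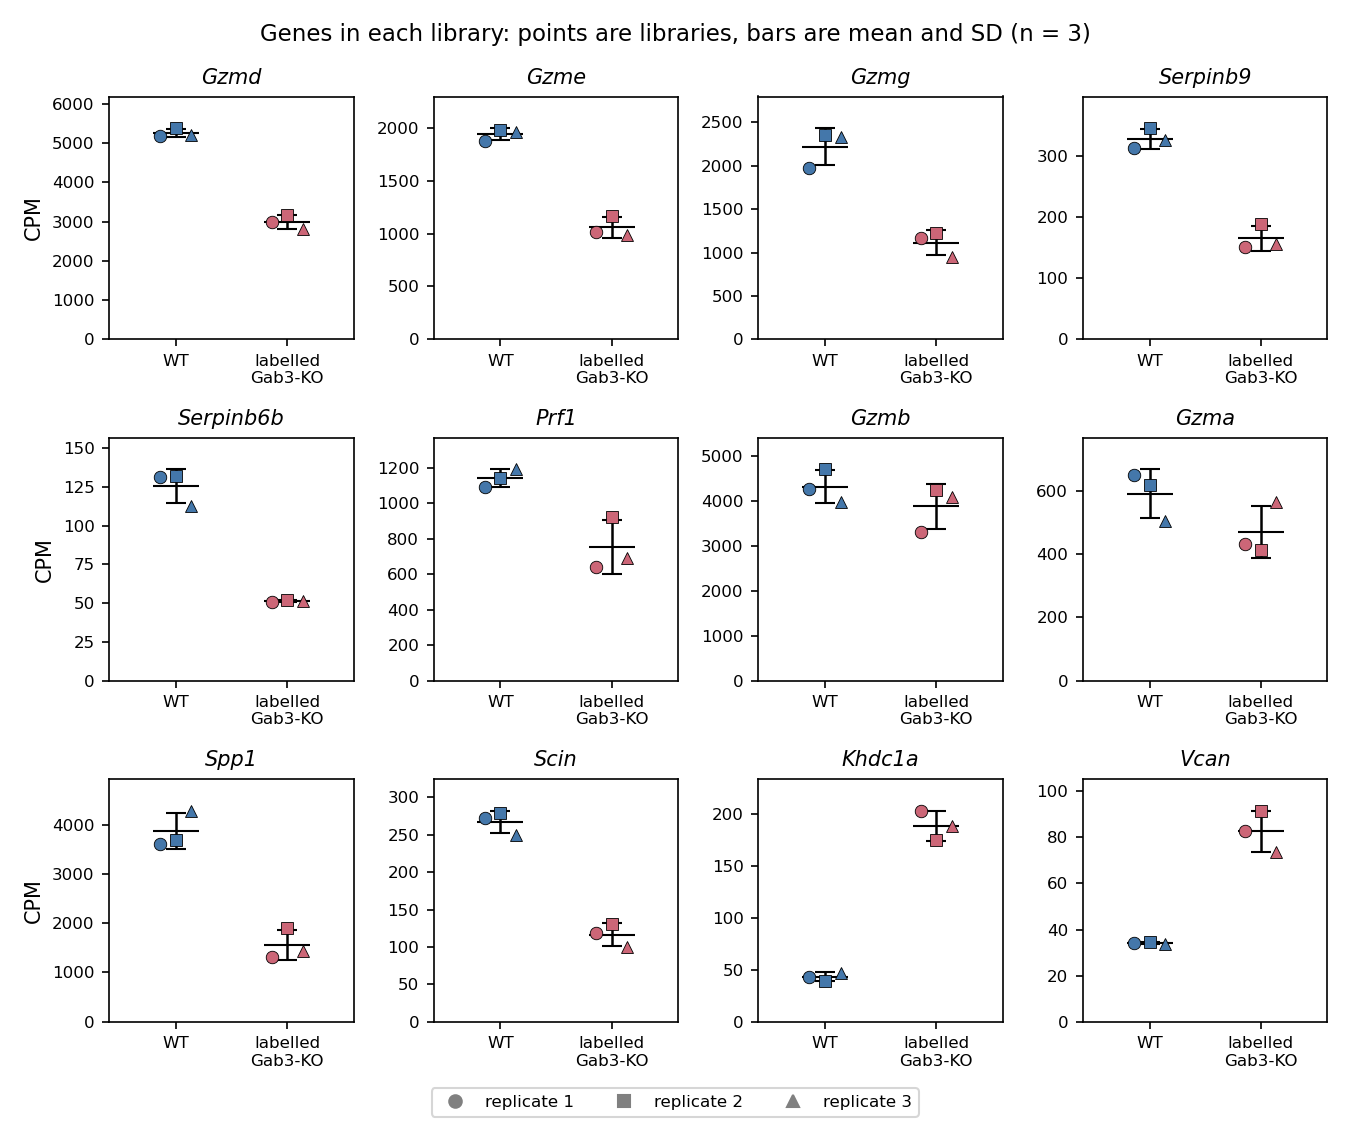
CPM (vertical axes, each linear from 0) of 12 genes in the 3 WT libraries and the 3 libraries labelled Gab3-KO; points are libraries and bars give mean and SD. Gzmd, Gzme, Gzmg, Serpinb9, Serpinb6b, Spp1 and Scin lie lower and Khdc1a and Vcan higher in every library of the second group. Prf1, which was not called, also lies lower in every library of that group, whereas the Gzmb and Gzma values of the groups overlap.

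Receptors of NK cells were lower as a list by camera with the preset correlation and by fry, but not with an estimated correlation (adjusted p = 0.17 with an estimated correlation), and few were called singly. Of 32 tested members, 2 were lower and 0 higher over all genes, and 9 were lower when adjusted over the list alone. Havcr2, which encodes the inhibitory receptor TIM-3, dropped from 182 ± 18.7 to 104 ± 6.12 CPM (log2 fold change -0.81, SE 0.13). Klra7, a Ly49 receptor gene with close paralogs and so of uncertain value, decreased by 0.73 (SE 0.12). Klra7 was not called after correction for GC content and transcript length, with or without the replicate block. Klrk1, the gene of the activating receptor NKG2D, was at -0.59 (SE 0.13, adjusted p = 0.13), Ncr1 at -0.36 (SE 0.12) and Klrb1c at -0.21 (SE 0.13), none of which passed over all genes. The median was -0.35, and the list had an adjusted p of 1.60e-07 by camera and 0.0174 by fry. All 19 NK lineage genes, some of them in this list, had negative fold changes. With WT replicate 1 or Gab3-KO replicate 3 left out, 0 of the members were called.

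Transcription factors of NK cells were not called over all genes. Eomes, a defining factor of the lineage, was at 285 ± 12.3 CPM in WT and 250 ± 25.9 CPM in the libraries labelled Gab3-KO (log2 fold change -0.19, SE 0.11), and Tbx21 was at -0.56 (SE 0.25). Nr4a2, Id2 and Zbtb32 were lower when adjusted over the list alone, as 3 of 25 tested factors, and 0 of 25 over all genes. Of 21 tested genes of tissue residency, 1 was lower. Itga1, the gene of CD49a, an integrin that marks tissue-resident NK cells, fell from 435 ± 26.6 to 287 ± 24.3 CPM (-0.60, SE 0.10, adjusted p = 0.0275). That call held only without Gab3-KO replicate 1, and in the other 5 fits with 1 library left out its adjusted p was up to 0.281. Adjusted over the list alone, Itga1 was lower and Tmem176b higher. Itgae was at -0.24 (SE 0.63), with a log2 fold change of 0.46 without WT replicate 1, and Itga2 at -1.46 (SE 1.23). Cxcr6 had 76 reads in WT and 0 in the libraries labelled Gab3-KO, and did not pass. Of 17 genes of circulating NK cells, 0 were called over all genes or over the list alone.

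Among targets of ERK signalling, Spred1, a feedback inhibitor of the pathway, dropped from 131 ± 12.7 to 69.2 ± 5.88 CPM (log2 fold change -0.92, SE 0.14, adjusted p = 0.0156). It was the single call over all genes among 19 tested members. Adjusted over the list alone, Spry4, another feedback inhibitor, was lower too (-1.36, SE 0.32, adjusted p over all genes 0.22). The list, with a median of -0.26, did not pass by camera (adjusted p = 0.298). Without WT replicate 1, WT replicate 3, Gab3-KO replicate 2 or Gab3-KO replicate 3, Spred1 was not called, with adjusted p-values of up to 0.129. In IL-2 and IL-15 receptor signalling, 1 of 22 tested genes was lower over all genes. This was Ccnd2, a G1 cyclin gene, at 152 ± 14.0 and 90.4 ± 4.39 CPM (-0.75, SE 0.13), whose adjusted p was up to 0.252 with 1 library left out. Adjusted over the list alone, Ccnd2 and Prf1 were lower and Pim1 higher. Il2rb, a receptor chain used in the sort as CD122, was at 1333 ± 59.2 and 1190 ± 251 CPM (-0.16, SE 0.12), and Myc was at -0.26 (SE 0.16). Of 24 genes of Gab, Grb2 and PI3K signalling, 0 were called over all genes or over the list alone.

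Proliferation genes did not separate the groups in this test. None of 23 genes of mitosis and none of 26 genes of DNA replication was called by edgeR over all genes or over the list alone, with medians of 0.01 and 0.04. Mki67, a marker of cycling cells, was at 426 ± 21.0 CPM in WT and 507 ± 56.0 CPM in the libraries labelled Gab3-KO (log2 fold change 0.25, SE 0.10, adjusted p = 0.651). Without Gab3-KO replicate 1 the DNA replication list was higher by camera with the preset correlation of 0.01 (median 0.15, adjusted p = 0.00903). The correlation estimated for this list from all 6 libraries was 0.284, and camera with it gave an adjusted p of 0.894 there. It was not run without that library, so the call may rest on members that move together.

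Interferon-induced genes were higher as a list only by camera with the preset correlation, with 0 of 30 members called over all genes and 8 higher when adjusted over the list alone. Ifit2 was at 304 ± 8.53 CPM in WT and 418 ± 40.1 CPM in the libraries labelled Gab3-KO (log2 fold change 0.46, SE 0.10, adjusted p = 0.13). The median was 0.21. The list passed by camera (adjusted p = 7.84e-05) but not by fry (0.172) and not with the correlation taken from the data (adjusted p = 0.525 with an estimated correlation). Without Gab3-KO replicate 1 the median was 0.13 (adjusted p = 0.00903 by camera). The same held for immediate early and dissociation stress genes. Of 21 tested members, 1 rose over all genes, Zfp36, and 6 were higher when adjusted over the list alone, among them Fos (488 ± 30.7 and 672 ± 32.5 CPM, 0.46, SE 0.09) and Atf3 (0.66, SE 0.14). The median was 0.26. The list had an adjusted p of 1.01e-05 by camera and an adjusted p = 0.717 with an estimated correlation, and fry gave 0.177. In the unfolded protein response, 0 of 22 were called over all genes and 3 were lower when adjusted over the list alone: Calr, Pdia4 and Manf.

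Of 15 tested angiogenic and growth factor genes, Spp1 was the single call over all genes and over the list alone. Vegfa was at 14.7 ± 3.29 CPM in WT and 12.9 ± 5.83 CPM in the libraries labelled Gab3-KO (log2 fold change -0.20, SE 0.41). Of 23 cytokine and chemokine genes, 0 were called over all genes or over the list alone. Csf2 had 61 reads in WT and 0 in the other group and did not pass. Ifng, Il2rg and Bcl2 had no row under these symbols in the table used here.

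**Figure D3:**
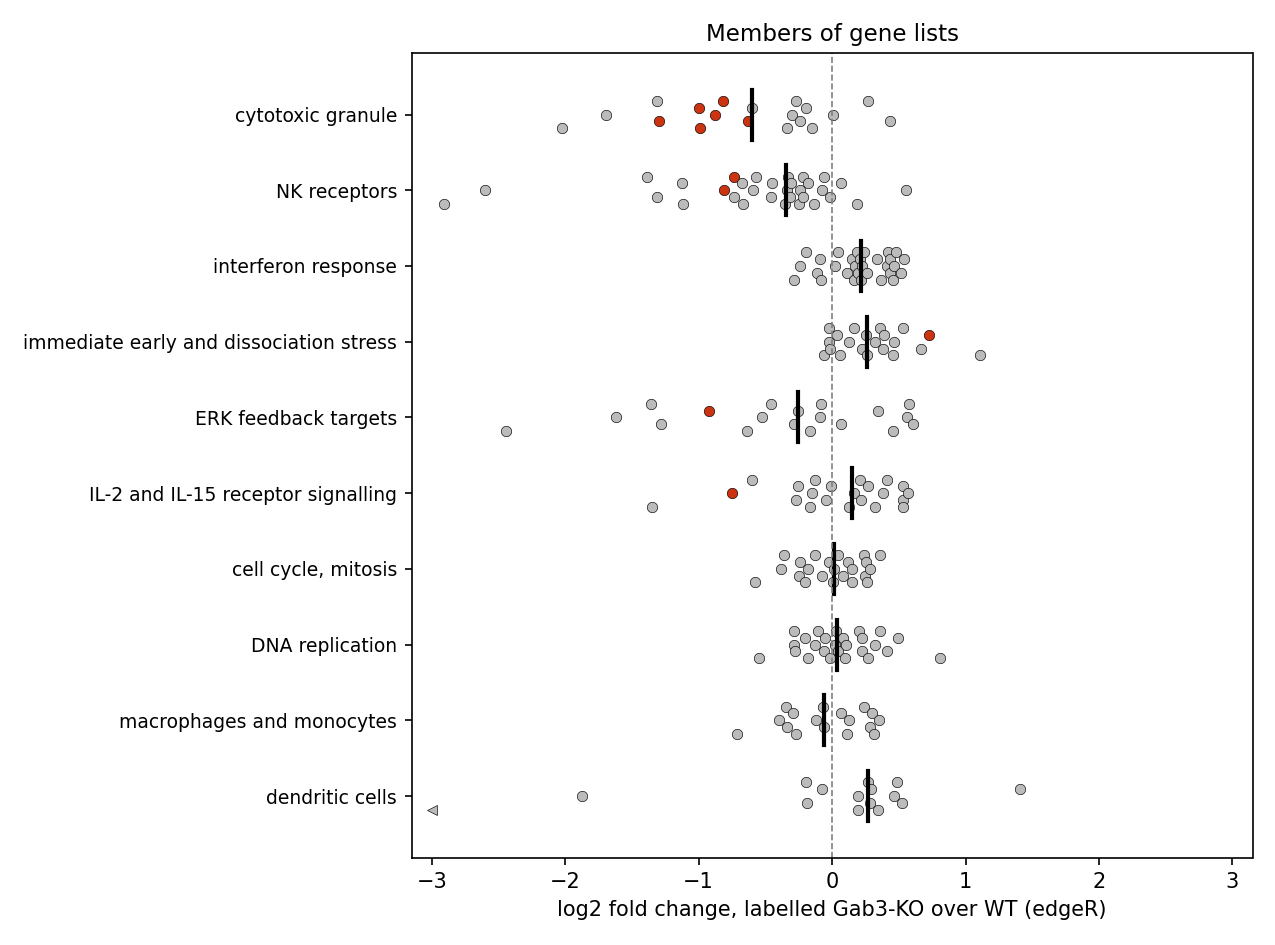
Log2 fold change (horizontal axis, libraries labelled Gab3-KO over WT, edgeR) of each tested member of 10 gene lists; red points passed the test over all genes, grey points did not, vertical bars are medians, and 1 member beyond 3 is drawn as a triangle at the edge. The medians of the cytotoxic granule and NK receptor lists are -0.60 and -0.35, and those of the interferon and immediate early lists 0.21 and 0.26.

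Transcripts of myeloid cells were abundant in every library although the sort took CD122-positive cells. Counts of the sorted population therefore do not show which cells carried a called gene, whether higher or lower. Lyz2, the gene of lysozyme in macrophages, stood at 1691 ± 195 CPM in WT and 2101 ± 183 CPM in the libraries labelled Gab3-KO (log2 fold change 0.31, SE 0.10, adjusted p = 0.416), and Cd74, the invariant chain of MHC class II, at 2630 ± 224 and 3209 ± 197 CPM (0.29, SE 0.08, adjusted p = 0.337). Neither passed, while every single value of Lyz2 and Cd74 in the second group exceeded every WT value. Of all tested genes, 14.2% had no overlap between the groups in 1 direction or the other. None of 17 macrophage and monocyte genes and none of 15 dendritic cell genes was called over all genes or over the list alone. The macrophage list had a median of -0.06 with 9 of 17 fold changes negative, among them C1qa (-0.35, SE 0.29), Cd14 (-0.40, SE 0.29) and Pf4 (-0.71, SE 0.55), named after their values were seen. The dendritic cell list passed by camera only with the filter at 10 CPM (median 0.29, adjusted p = 0.00255). Of 13 B cell genes, Jchain rose over all genes and over the list alone. The B cell list had a median of 0.64 (also with Jchain at its bound). It passed by camera (adjusted p = 0.0396), but not with RLE factors (0.0551), upper-quartile factors (0.056) or library size only (0.0751), nor with the 10 CPM filter (median 0.20, 0.556) or the GC and length correction (0.0574). It did not pass without Gab3-KO replicate 1 (0.534), WT replicate 1 (0.158) or WT replicate 2 (0.0566). With 1 library left out the median was 0.37 to 1.11, and the list had an adjusted p = 0.826 with an estimated correlation. Of 6 tested T cell genes, 0 were called over all genes or over the list alone, and Cd3e had reads in only 2 libraries and was not tested.

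Between pairs of libraries of 1 group, the chi-square per degree of freedom was 38.2 to 73.9 in the libraries labelled Gab3-KO and 19.002 to 33.7 in WT. In a principal component analysis, Gab3-KO replicate 1 stood alone on the first component (33.7% of the variance) and Gab3-KO replicate 2 on the second (26.9%). The calls differed in how far they rested on single libraries. Khdc1a, Gzmd, Gzme, Scin, Gzmg, Spp1, Serpinb6b, Serpinb9, Ear3 and Car2, 10 of the 26, were called in each of the 6 fits that left out 1 library. The other 16 were lost in at least 1 such fit. These fits called 14 genes without WT replicate 1, 13 without Gab3-KO replicate 3, and 21, 23, 36 and 20 without WT replicate 2, WT replicate 3, Gab3-KO replicate 1 and Gab3-KO replicate 2. DESeq2 called 287 genes, including all 26.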

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

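The tests of ribosomal protein genes and the cut-offs on the lineage list were chosen only after results were seen; all other alternatives were fixed beforehand. Against 26 genes called (8 higher, 18 lower), DESeq2 called 287 (135 higher, 152 lower), of which 187 had a group mean over 64 CPM, and no filter gave 98 (43 higher, 55 lower); all 26 were among both. Without robust moderation 4 genes were higher and 20 were called in all. An adjusted p below 0.01 left 13 (2 higher, 11 lower), and a test against a fold change of 1.5 left 8 (2 higher, 6 lower), both by construction stricter. The 3 other scalings gave 27 to 28 genes, limma-voom 35 (20 shared), the 10 CPM filter 30 (22 shared) and the GC and length correction 30 (24 shared). Leaving out 1 library gave 13 to 36 called, 2 to 8 higher and 10 to 28 lower, and 4 to 6 lists. The lists called went from 5 to 0 with an estimated correlation and to 2 with fry. With 1 library left out, values changed sign for Gab3 (-0.12 to 1.29), Itgae (-0.51 to 0.46), Vegfa (-0.60 to 0.072), Gab1 (-1.47 to 0.36, with 0.000708 without WT replicate 1 and 0.09 without Gab3-KO replicate 3) and Gab2 (-0.072 to 0.17), none of which was called in any of these fits. The cause of the other differences was not tested. Khdc1a, Gzmd, Gzme, Scin, Serpinb6b, Serpinb9 and Car2, 7 of the 26, were called under all 17 other fits. Among the other values of genes and lists, 2615 stayed alike in direction and side of the threshold (or in count), 81 lost a call, 44 gained one and 58 moved.

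The medians of 25 of the 37 lists changed sign under at least 1 alternative, and the cause was not tested. There were 98 such medians, and in 1 of these cases the list was called by camera, that of trophoblast without WT replicate 1. With 1 library left out, the medians were -0.13 to 0.20 for mitosis, -0.0359 to 0.15 for DNA replication, -0.00167 to 0.16 for IL-2 and IL-15 signalling and -0.0186 to 0.0707 for Gab, Grb2 and PI3K signalling. They were -0.26 to 0.0461 for cytokines, -0.13 to 0.0661 for tissue residency, -0.0147 to 0.21 for circulating NK cells and -0.0479 to 0.0969 for glycolysis. Those of oxidative phosphorylation were -0.18 to 0.0466, of cholesterol synthesis -0.10 to 0.0294, of apoptosis -0.00477 to 0.0645 and of adhesion -0.0467 to 0.0753. Those of histones were -0.15 to 0.63, of the neighbours of Gab3 -0.0519 to 0.0501, of T cells -0.36 to 0.83 and of macrophages -0.088 to 0.0709. Those of mast cells and allied granulocytes were -0.23 to 0.44, of helper lymphoid cells -0.0801 to 0.42, of epithelium -0.17 to 0.67 and of trophoblast -6.83 to 0.62. Those of endothelium were -0.0605 to 0.47, of erythroid cells -0.29 to 0.98 and of Y-linked genes -1.42 to 1.22. RLE factors gave glycolysis 0.0165, oxidative phosphorylation 0.00803, adhesion 0.00764 and neighbours of Gab3 0.0103. Upper-quartile factors gave 0.0167, 0.00722, 0.0074 and 0.0102 for these 4, library size only 0.0325, 0.0234, 0.023 and 0.026, and the 10 CPM filter 0.027, 0.00674, 0.00644 and 0.0658. That filter also gave T cells -0.33, helper lymphoid cells -0.23, stroma -0.0849, epithelium -0.58 and erythroid cells -0.71. No filter gave neighbours of Gab3 0.0463, macrophages 0.00143, mast cells and allied granulocytes 0.79, epithelium -0.59 and trophoblast -4.20. The replicate block gave glycolysis 0.0129, histones -0.14, neutrophils -0.46, epithelium -0.14, trophoblast -0.038, endothelium -0.62, erythroid cells -1.25 and Y-linked genes -0.43. The GC and length correction gave tissue residency -0.00404, glycolysis 0.0562, oxidative phosphorylation 0.067, adhesion 0.0298 and neighbours of Gab3 0.0305. With the block as well, the first 4 of these were -0.00313, 0.0548, 0.0533 and 0.00215, beside histones -0.000774, neutrophils -0.35, epithelium -0.0768, endothelium -0.61, erythroid cells -1.21 and Y-linked genes -0.47.

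Nothing states that equal replicate numbers pair libraries. The deviations of same-numbered libraries correlated at 0.017, -0.003 and 0.030, and only those of number 3 correlated best with their own number. With the replicate number as a block, 32 genes were called, including all 26, and with the block and the GC and length correction 28, of which 22 were shared.

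Of simulated 1.5-fold changes of single genes, 5.47% were called, and 10 of 50 in genes over 64 CPM, so a single gene without a call is not shown to be unchanged at that size. The list raised 1.5-fold was called in 3 of 3 simulations, but its members were genes over 64 CPM that varied independently of each other. It therefore does not show that an uncalled list was unchanged. Nor does it show how camera with the preset correlation treats lists whose members move together.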

Other observations

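The tests of granule genes against NK lineage genes and of the summed granzymes, and all tests of ribosomal protein genes as a group, were chosen only after results were seen. Of 7 tested genes of mast cells, basophils and eosinophils, 3 had positive and 4 negative fold changes, 0 were called over all genes, and the list did not pass by camera (adjusted p = 0.186). Kit, a growth factor receptor of mast cells (31.8 ± 10.4 CPM in WT, 14.3 ± 4.43 CPM in the libraries labelled Gab3-KO, SD, n = 3 each), and Mcpt8, a basophil protease (9.88 ± 0.588 and 2.74 ± 0.845 CPM), were lower when adjusted over the list alone. Of 8 neutrophil genes, 0 were called over all genes and Chil3 (95.2 ± 4.27 and 142 ± 14.7 CPM) was higher when adjusted over the list alone. The metallothionein genes Mt1 (85.9 ± 24.8 and 40.9 ± 10.9 CPM, log2 fold change -1.07, SE 0.25) and Mt2 (82.3 ± 5.57 and 38.4 ± 18.4 CPM, -1.11, SE 0.27) did not pass over all genes. Slc39a14, which imports zinc, was among the lower calls, but in only 3 of the 6 fits that left out 1 library.

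Several other programmes held no calls by edgeR over all genes or over the list alone. These were glycolysis and hypoxia (26 genes tested), oxidative phosphorylation (30), cholesterol synthesis (21), amino acid transport and ATF4 targets (24), ribosome biogenesis (26), apoptosis regulators (21), adhesion and migration (25), replication-dependent histones (9) and the neighbours of Gab3 on the X chromosome (22). The same held for markers of helper innate lymphoid cells (8), decidual stroma (14), uterine epithelium (4), trophoblast and yolk sac (2), endothelium (12), erythroid cells and platelets (5) and Y-linked genes (2). With 1 library left out, camera with the preset correlation called the endothelium list without Gab3-KO replicate 1 (median 0.47, adjusted p = 0.00903). It also called the trophoblast list without WT replicate 1 (median -3.41, adjusted p = 0.043). Over all 13935 genes, 980 passed an unadjusted p of 0.05 and DESeq2 called 287. Of the 10 splits of the 6 libraries into 3 and 3, 1, the real one, gave as many as 26 called genes, and the highest of the others gave 3. So few splits cannot give a share under 0.05.

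All 19 tested NK lineage genes had negative fold changes, with a median of -0.36 (camera p = 0.011 with an estimated correlation, unadjusted). The lineage list was added after results were seen. It shares members with the NK receptor list, which was already lower by camera with the preset correlation. The unadjusted value is therefore no independent test and cannot be set against the adjusted values of the lists fixed beforehand. None of the 19 was called by edgeR over all genes and 5 were lower when adjusted over the list alone. Klrc2 (8.25 ± 1.56 CPM in WT, 1.35 ± 1.24 CPM in the libraries labelled Gab3-KO), Klrc1 (24.3 ± 6.02 and 9.31 ± 4.97 CPM) and Sh2d1b2 (12.9 ± 1.76 and 5.85 ± 1.97 CPM) were among the lineage genes that did not overlap between the groups. Over all tested genes, 14.2% had no overlap, where 10% are expected by chance. Of genes of other cells, Lyz2 (log2 fold change 0.31), Cd74 (0.29), Fcgr1 (0.35), Ms4a6c (0.24) and H2-Aa (0.27) were not called, with every value of the second group above every WT value. Among all tested members of their lists, 9 of 17 macrophage and monocyte genes and 5 of 15 dendritic cell genes had negative fold changes. The genes of both kinds named here were chosen after their values were seen, and a smaller share of NK cells was not excluded for the NK receptor list.

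The 6 granule genes called lower had a median log2 fold change of -0.93. A smaller share of NK cells in the sorted population would lower NK lineage genes alike. The ratio of granule to lineage genes within a library differed by -0.25 (SE 0.17) over all 19 and the groups overlapped. Cut-offs on the mean level over all 6 libraries, tried only then, gave -0.48 to -0.67 at 7 levels from 5 to 200 CPM with no overlap. Such cut-offs also use the values of the libraries labelled Gab3-KO, so they can drop lineage genes that fell. Cut-offs on the WT mean gave -0.25 with overlap at 5 CPM, which kept all 19, and -0.48 to -0.63 with no overlap from 10 to 200 CPM. At 64 CPM both rules selected the same 12 genes and gave -0.60 (SE 0.06). All 13 granule genes at that WT level, chosen without regard to calls, differed from these 12 by -0.24 (SE 0.03) with no overlap. The 6 called genes carried this difference, since the 7 not called differed from the 12 by 0.06 (SE 0.03) and the groups overlapped. The 6 were picked as low in these same libraries, and the cut-offs were tried only after the first ratio overlapped. The values therefore cannot decide whether a smaller share was the whole cause for the 6. They show only that at 64 CPM the 13 granule genes together fell further than the 12 lineage genes, through the 6 called. A smaller share as the whole or a part of the cause stays open, since the 12 lineage genes themselves differed by -0.33 (SE 0.05). Correcting for GC content and length left a median of -0.77 with 5 of the 6 called (Gzmf moved from -0.63 to -0.47, SE 0.08 before). The log2 sum of Gzmb, Gzmd, Gzme, Gzmf, Gzmg and Gzmn differed by -0.61 with no overlap of the groups. Neither a composition trend nor reads moved among these granzymes therefore accounts for the whole. Gzmc had no row, and how reads that match several genes were handled is not given. Reads discarded or assigned outside the sum were not tested. A change within the cells and a different mix of NK cell subsets both stay open, since the lists of tissue residency (adjusted p = 0.933 by camera, Itga1 called lower) and of circulating NK cells (0.691) did not pass, with members that went both ways.

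The library labelled Gab3-KO replicate 1 held 84.1 CPM of Gab3, over 3 times any other library. Uneven amplification would give other such genes, but of 3878 genes at 10 to 40 CPM in the other libraries, Gab3 was the single one at least 3 times as high there as in each other library (0.0258%). A WT library under the wrong label would lie with WT, but at 80.6% of the genes called without it (29 of 36, exact 95% interval 63.98% to 91.8%, which treats genes as independent) it lay nearer to the other libraries labelled Gab3-KO, all 6 granule genes among them. Both tests argue against these causes. A difference of the altered Gab3 allele or its transcripts between animals may account for the level, and counts per gene cannot test it.

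Ribosomal protein genes were lower as a group in the libraries labelled Gab3-KO, with 75 of 78 fold changes negative, a median of -0.26 0 called over all genes and 47 lower when adjusted over the list alone (p = 6.27e-16 by camera, p = 0.145 with an estimated correlation). Without Gab3-KO replicate 1 the median was -0.25, which argues against that library as the cause. After correction for GC content and length it was -0.16, between the bounds set for a trend and for none, so a trend of the counts on composition and a change of the cells cannot be told apart. These genes are short and strongly expressed, and the correction was fitted on the same libraries.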
